A study of Mus musculus with 6 samples.

How the data were processed

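Messenger RNA from mouse yolk sacs at embryonic day 9.5 was sequenced in 6 libraries. Per the labels, 3 came from untreated wild-type (WT) CD1 embryos and 3 from embryos of mixed background labelled DKO, which lack Cdx1, carry a Cdx2 allele with loxP sites and a tamoxifen-activated Cre driven by an actin promoter, and received tamoxifen at embryonic day 5.5. Genotype, strain and tamoxifen therefore differ together between the 2 groups, and no comparison of these libraries separates them. The labels do not say whether a sample is a single yolk sac or a pool, or whether samples came from separate litters, so p-values measure only the spread between these samples.

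The authors deposited raw read counts per gene symbol, and the counts were used as deposited. Per the submitters' processing notes, the build was mm10 and SAMtools and DESeq2 were used, with no version or role stated. The column headers of the deposited counts name BAM files that were subsets, and what was subset is not stated. The aligner, the counting program, the gene annotation and the strand setting are not given in the sources used here. Per the labels' protocols the reads were single-end, from RNA purified on columns. Counts cover whole genes, so reads from a deleted exon cannot be told from reads of the remaining exons, and reads of near-identical genes may have been dropped or split. The adult globin symbols Hba-a1, Hba-a2, Hbb-bs and Hbb-bt held between 0 and 2 counts in each library, and the share of counts in globin genes is therefore a share of what was counted. None of the 13 mitochondrially encoded symbols listed matched a row, and that list was not analysed here.

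The table held 25239 genes, of which 5183 had no count in any library. There were 0 rows without a gene name and 0 columns without a sample. Coordinates came from a RefSeq table of GRCm38, the assembly that mm10 names, in which 25041 symbols matched. Library totals ran from 20040601 to 56732836 counts, and 3 counts corresponded to between 0.0529 and 0.15 CPM, that is, counts scaled to a common library size. Intervals of single counts are exact Poisson intervals at 95% and cover counting error only.

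Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group, robust shrinkage and group as the only term. The filter kept 14002 genes. Adjusted p-values are Benjamini-Hochberg values over these genes with a threshold of 0.05. Standard errors were taken as the absolute log2 fold change over the square root of F. All fold changes are libraries labelled DKO minus WT. Gene lists, 34 in number, were fixed before the data were examined, and 32 had at least 3 tested members. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Single measures were compared by exact permutation of 3 against 3 libraries, whose smallest two-sided p is 0.1.

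Genes were named by a rule fixed before the data were examined. It takes Cdx1, Cdx2 and Cdx4. It takes up to 8 genes up and 8 down past the threshold with a mean of at least 5 CPM and groups that do not overlap, without predicted or sex-linked genes. It takes the 3 members with the smallest adjusted p of each list that passed camera. For the erythroid, progenitor, endothelial, visceral endoderm and Hox lists it otherwise takes the 2 members with the highest mean CPM. A gene that the rule takes is not reported here. Genes named outside the rule were chosen after their values were seen, and are Vill, Col4a5, Lin28b, Esr1, Hbb-bh1, Hbb-y, Xist and the genes near Cdx1 and Cdx2 given with the closing observations.

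The test was tested on simulated data for the 3 against 3 comparison over 14002 genes with 200 changed. With the spread estimated from all 6 libraries it recovered 41% of 2-fold and 78% of 4-fold changes, and 11 of 130 calls were false. With the spread of the WT libraries it recovered 87% and 96%, and 17 of 200 calls were false. A simulation with no changed genes gave 0 calls. Both simulated groups had the same spread and independent genes, whereas the libraries labelled DKO differed from each other more than the WT libraries did. The simulated shares may therefore not hold for these data. In 10 simulated draws camera called the shifted list 10 times, and called 1 of 310 unshifted lists, with genes drawn independently. In the data the estimated correlation between members was 0.85 for cholesterol synthesis and 0.785 for primitive erythroid genes. The simulated rates may therefore not hold for such lists.

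Alternatives were DESeq2 1.42.0, limma-voom without and with library quality weights, other scaling factors, other filters, globin genes left out, robust shrinkage off, a stricter threshold of 0.01, a block for replicate number, a term for Y-linked expression, camera with an estimated correlation, fry, lists without shared members, and each library left out in turn. Chosen after seeing the data were a term for the ratio of Hbb-bh1 to Hbb-y (the stage term), leaving out both libraries 1 and 3 labelled DKO, and thinning all libraries to the smallest total.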

Results

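The series profiled yolk sacs of mouse embryos at embryonic day 9.5, when this extraembryonic membrane makes blood and its vessels remodel. It set 3 wild-type (WT) libraries against 3 labelled DKO, from embryos mutant for the caudal homeobox genes Cdx1 and Cdx2 and given tamoxifen at embryonic day 5.5. WT libraries 1, 2 and 3 held 26855337, 20532298 and 20040601 counts. Libraries 1, 2 and 3 labelled DKO held 24242663, 39014098 and 56732836 counts. Levels are given as CPM (counts scaled to library size).

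The targeted gene Cdx2 was not lower in the libraries labelled DKO. Its level was 16.7, 18.9 and 20.5 CPM in WT libraries 1, 2 and 3 and 23.4, 24 and 25.1 CPM in libraries 1, 2 and 3 labelled DKO, from 389 to 1422 counts per library. The log2 fold change was 0.38 (SE 0.12), with an adjusted p of 0.449 from edgeR, so the groups did not differ past the threshold although all 3 libraries labelled DKO lay above all 3 WT. Cdx1 was near the limit of detection, with 0, 1 and 8 counts in WT and 10, 14 and 14 counts in the libraries labelled DKO, and was removed by the filter. Cdx4 had 0, 1 and 1 counts in WT and 0 in each library labelled DKO, where 3 counts would be 0.0529 to 0.124 CPM. In GRCm38, Cdx2 lies on chromosome 5 from 147300900 to 147307249, Cdx1 on chromosome 18 from 61018862 to 61036199 and Cdx4 on chromosome X from 103321398 to 103330224. The counts span whole genes and do not show whether the exons meant to be deleted were read. Because Cdx1 and Cdx2 do not separate the groups as their labels would, every direction given for the libraries labelled DKO rests on the labels.

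The 3 libraries labelled DKO differed from each other more than the WT libraries did. Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.989 to 0.990 between WT libraries and 0.925 to 0.969 between libraries labelled DKO. Correlations between the groups ran from 0.937 to 0.981. The first principal component took 58.4% of the variance and placed library 3 labelled DKO at 78 and library 1 at -35.3, with the WT libraries between -27.1 and -12. No pair agreed within sampling noise, the lowest chi-square per degree of freedom being 11.9. The biological coefficient of variation over all libraries was 25.9%.

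**Figure D1:**
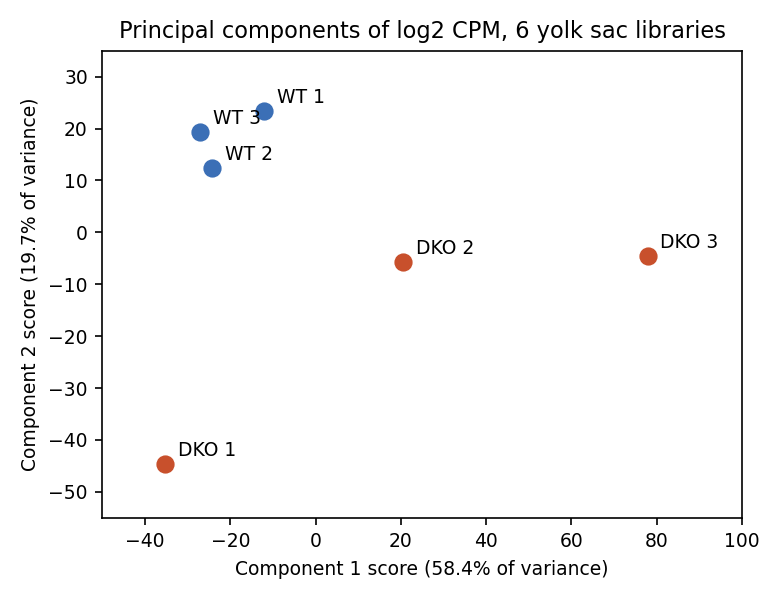
Scores of the 6 libraries on the first and second principal components of log2 CPM (arbitrary units, WT in blue, labelled DKO in orange). Library 3 labelled DKO sits at 78 on component 1, and library 1 at -44.7 on component 2, away from the WT libraries.

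Of 14002 genes tested, 2 were higher and 3 lower in the libraries labelled DKO, all by at least 2-fold. Rpl21, a ribosomal protein gene, rose from 3.66 ± 0.819 CPM (SD, n = 3) to 131 ± 20.5 CPM (n = 3), a log2 fold change of 5.15 (SE 0.23, adjusted p 0.0026 by edgeR). Col4a6, a basement membrane collagen chain, fell from 15.6 ± 3.42 to 0.389 ± 0.129 CPM, a log2 fold change of -5.27 (SE 0.33, adjusted p 0.0112). Prkg2, a cGMP-dependent protein kinase, fell with a log2 fold change of -2.77 (SE 0.21, adjusted p 0.0225). Cd276, an immune checkpoint molecule, fell with a log2 fold change of -1.51 (SE 0.11, adjusted p 0.0221). Vill, a villin-like actin-binding protein gene, rose from 1.68 ± 0.191 to 8.02 ± 1.03 CPM (log2 fold change 2.25, SE 0.21, adjusted p 0.0485). It lies under the 5 CPM needed by the naming rule and was named after its values were seen. In each of these genes the 3 libraries labelled DKO lay on one side of the 3 WT libraries.

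In GRCm38, Rpl21 lies on chromosome 5 from 146832890 to 146837032, 464 kb from Cdx2, and Prkg2 on chromosome 5 from 98929773 to 99037375. Col4a6 lies on chromosome X from 141165403 to 141474095, Cd276 on chromosome 9 from 58524300 to 58555033 and Vill on chromosome 9 from 119052729 to 119071525. Ribosomal protein genes have many processed copies, and the value of Rpl21 is uncertain where the authors' counting could split such reads. Col4a5, the neighbour of Col4a6 on chromosome X, stood at 41.6 ± 3.57 CPM in WT and 40.5 ± 9.89 CPM in the libraries labelled DKO (adjusted p 0.947 by edgeR).

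At an unadjusted p under 0.05, 1273 genes were counted, 777 higher and 496 lower, where 700 would be expected by chance. In 2178 genes (15.6%) the groups did not overlap, where chance gives 10%. DESeq2 called 177 genes higher and 119 lower. The count of 5 turned on single libraries: edgeR called 634 genes without library 1 labelled DKO and 8 without library 3. It called 1 gene, Rpl21, without WT library 1, WT library 3 or library 2 labelled DKO, and 0 without WT library 2, where 630 genes had an unadjusted p under 0.05. The fold changes moved little when each library was left out in turn, from 4.97 to 5.28 for Rpl21, 2.14 to 2.35 for Vill, -5.45 to -5.08 for Col4a6, -2.88 to -2.62 for Prkg2 and -1.57 to -1.45 for Cd276.

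**Figure D2:**
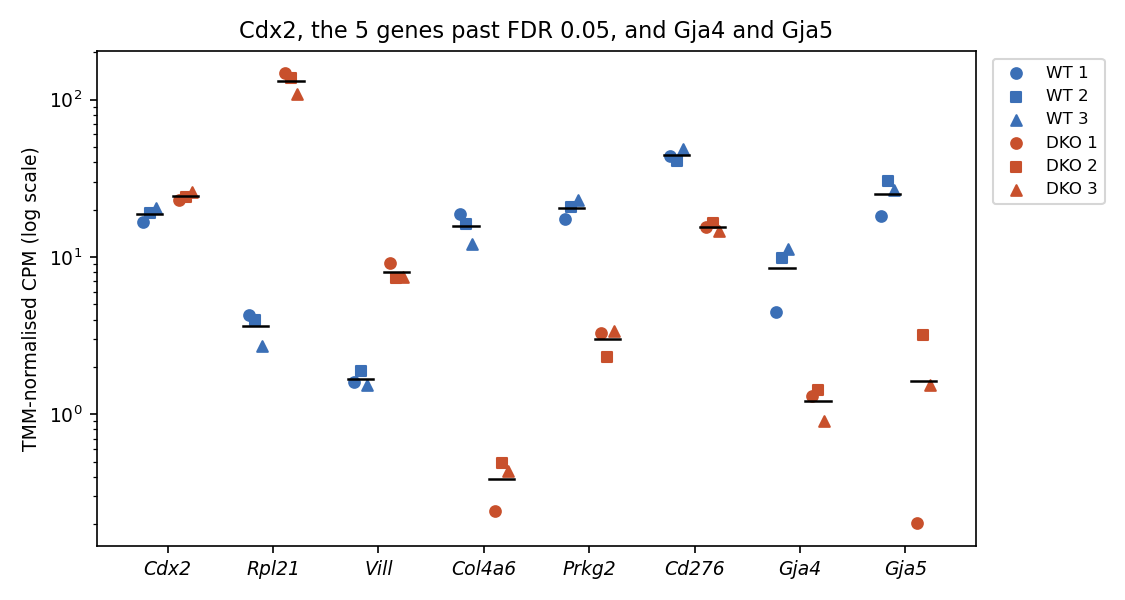
TMM-normalised CPM on a log axis in each library for Cdx2, the 5 genes past the threshold, and Gja4 and Gja5, with bars at group means (WT in blue, labelled DKO in orange). Rpl21 lies between 2.73 and 4.27 CPM in WT and between 108 and 147 CPM in the libraries labelled DKO, while Cdx2 is no lower in the latter.

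Of the 32 lists tested, 12 passed camera with the preset correlation, 5 lower and 7 higher in the libraries labelled DKO. None passed with an estimated correlation, where adjusted p was 0.84 for 11 of these lists and 0.89 for heme synthesis and iron uptake. The shared value of 0.84 comes from the adjustment over lists. Unadjusted, the p of this camera test ran from 0.038 for hypoxia and glycolysis (estimated correlation 0.055) to 0.43 for heme synthesis and iron uptake (0.371). No list had a member past the threshold of edgeR over all genes, so members are given as values.

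The primitive erythroid list and the list of heme synthesis and iron uptake were lower as sets. All 28 tested primitive erythroid genes had a negative fold change, with a median of -0.54 and an adjusted camera p of 3.11e-05 (0.84 with an estimated correlation). No member had an unadjusted p under 0.05 or was called by DESeq2. The median difference from WT was 0.08 in library 1 labelled DKO, -0.23 in library 2 and -2.36 in library 3. The erythroid nuclear protein gene Hemgn had a log2 fold change of -0.96 (SE 0.43), the anion exchanger Slc4a1 -0.92 (SE 0.49) and Bpgm, which makes 2,3-bisphosphoglycerate, -0.47 (SE 0.23). Heme synthesis and iron uptake had 16 of 22 members negative (median -0.21, adjusted p 0.0499, and 0.89 with an estimated correlation). Its mitochondrial iron importer Slc25a37 stood at -0.87 (SE 0.41) and Slc25a38 at -0.26 (SE 0.12), while Alad, an enzyme of the pathway, stood at 0.37 (SE 0.11). Globin genes took 1.08% ± 0.235 of counts in WT and 0.663% ± 0.368 in the libraries labelled DKO (SD, n = 3 each, exact permutation p = 0.2, smallest possible 0.1).

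The arterial, venous and Notch list had 14 of 24 members negative (median -0.14, mean -0.46, adjusted p 0.0159, and 0.84 with an estimated correlation). The gap junction genes of arterial endothelium, Gja4 and Gja5, had log2 fold changes of -2.82 (SE 0.41) and -3.90 (SE 0.76), with adjusted p of 0.135 and 0.247 by edgeR. Gja5 stood at 25.0 ± 6.24 CPM in WT and 1.64 ± 1.48 CPM in the libraries labelled DKO. The ephrin gene Efnb2, an arterial marker, stood at -1.09 (SE 0.30, adjusted p 0.385). Adjusted over the list alone, 2 members passed, both lower, and DESeq2 called 3 lower. Wnt targets had 18 of 21 members negative (median -0.34, adjusted p 0.00311, and 0.84 with an estimated correlation). Among them the secreted Wnt antagonist Dkk1 stood at -0.88 (SE 0.19) and Notum at -1.64 (SE 0.86), while Rnf43 stood at 0.60 (SE 0.34). The median difference from WT was 0.18, -0.60 and -0.81 in libraries 1, 2 and 3 labelled DKO. Without library 1 the list median was -0.69, Notum stood at -3.22 and Rnf43 at 0.26.

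The lists higher as sets covered hypoxia and glycolysis, cholesterol synthesis, immediate early genes, p53 targets, the interferon response, the NRF2 and AhR response and trophoblast markers. Hypoxia and glycolysis had 26 of 30 members positive (median 0.24, adjusted p 0.000154, and 0.84 with an estimated correlation), and 10 had an unadjusted p under 0.05, all higher. Its members included the glycolytic enzyme genes Pgk1 at 0.39 (SE 0.09) and Aldoa at 0.32 (SE 0.09) and Ankrd37 at 0.90 (SE 0.24). Cholesterol synthesis had 23 of 24 members positive (median 0.66, adjusted p 0.000149, and 0.84 with an estimated correlation), with Insig1, a regulator of sterol synthesis, at 1.47 (SE 0.45) and the enzyme gene Fdps at 0.66 (SE 0.26). Its median difference from WT was 0.11, 0.16 and 1.23 in libraries 1, 2 and 3 labelled DKO, and without library 3 the list had a median of 0.17 (adjusted p 0.097). Immediate early genes had 16 of 17 positive (median 0.54, adjusted p 0.000154, and 0.84 with an estimated correlation), with the transcription factor genes Egr1 at 1.46 (SE 0.25), Fos at 1.83 (SE 0.56) and Jun at 0.85 (SE 0.28). The median difference from WT of the immediate early genes was 0.09, 0.31 and 1.34 in libraries 1, 2 and 3 labelled DKO. Adjusted over the list alone, 1 immediate early gene was higher and no hypoxia or cholesterol gene passed.

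The p53 targets had 20 of 23 members positive (median 0.32, adjusted p 0.0024, and 0.84 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 0.58 (SE 0.18) and Gdf15 at 2.01 (SE 0.69) but Aen at -0.39 (SE 0.14). The interferon response had 13 of 15 positive (median 0.78, adjusted p 0.0239, and 0.84 with an estimated correlation), with Bst2 at 1.36 (SE 0.39), the RNA sensor Ddx58 at 1.11 (SE 0.41) and Tap1 at 1.65 (SE 0.71). Its median difference from WT was -0.04, 0.40 and 1.5 in libraries 1, 2 and 3 labelled DKO, and without library 3 the list had a median of 0.02 (adjusted p 0.31). The NRF2 and AhR xenobiotic response had 15 of 21 positive (median 0.38, adjusted p 0.0499, and 0.84 with an estimated correlation). Its glutathione transferase gene Gsta4 stood at 0.93 (SE 0.19) and Pgd at 0.44 (SE 0.12), while the drug efflux pump Abcb1b stood at -1.91 (SE 0.29). Adjusted over the list alone, 3 of these genes were higher and 2 lower.

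Trophoblast and placenta markers, which belong to a neighbouring tissue, had 11 of 12 members positive (median 1.94, adjusted p 0.00848, and 0.84 with an estimated correlation). The median difference from WT was 1.16, -0.78 and 2.19 in libraries 1, 2 and 3 labelled DKO. Rhox6 stood at 1.38 (SE 0.33), its paralog Rhox9 at 1.88 (SE 0.55) and the steroid enzyme gene Hsd3b6 at 2.01 (SE 0.52), and values of the paralogs are uncertain where reads were shared. Adjusted over the list alone, 3 were higher, and DESeq2 also called 3 higher. Of the 6 sex-linked genes, 5 were negative (median -0.78, adjusted p 0.00346, and 0.84 with an estimated correlation), including the Y-linked Eif2s3y at -0.79 (SE 0.19), Ddx3y at -0.78 (SE 0.21) and Kdm5d at -1.05 (SE 0.29). The summed Y-linked level was 95.8 ± 21.8 CPM in WT and 55.7 ± 10.3 CPM in the libraries labelled DKO (n = 3 each, exact permutation p = 0.1, the smallest possible). The X-inactivation transcript Xist stood at 120 ± 24.8 and 166 ± 37.5 CPM (n = 3 each, exact permutation p = 0.3). Each library held both Xist (97.65 to 209.1 CPM) and Y-linked counts (44.74 to 115.4 CPM). These values argue against tissue of a single sex in any library, so the Y-linked difference may follow the mix of sexes. Pools and maternal tissue were not told apart.

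Library 3 labelled DKO carried most list calls. Without it 4 of the 12 lists passed, namely hypoxia and glycolysis, p53 targets, immediate early genes and sex-linked genes, and primitive erythroid genes had a median of -0.12 (adjusted p 0.097). The medians without it were -0.09 for heme synthesis, -0.01 for arterial, venous and Notch genes, -0.16 for Wnt targets, 0.77 for trophoblast markers, 0.22 for the NRF2 and AhR list, 0.19 for p53 targets and 0.24 for immediate early genes. Genes named above from these lists whose log2 fold change then moved by over 1.5 times stood at -0.63 (Hemgn), -0.52 (Slc4a1), -0.30 (Bpgm), -0.51 (Slc25a37), 0.75 (Insig1), 0.31 (Fdps), 0.99 (Fos), 0.51 (Jun), 1.16 (Gdf15), 0.82 (Bst2), 0.65 (Ddx58) and 0.44 (Tap1). Bpgm stood at -0.72 without library 2. Without library 1 labelled DKO the calls of heme synthesis, of arterial, venous and Notch genes and of trophoblast markers were lost (adjusted p 0.064, 0.15 and 0.16), with medians of -0.30, -0.24 and 1.62 against -0.21, -0.14 and 1.94 with all libraries. The medians of primitive erythroid and immediate early genes without library 1 were -0.97 and 0.98, against -0.54 and 0.54. Without library 2 the call of the NRF2 and AhR list was lost (0.078), with a median of 0.33 against 0.38, and the median of Wnt targets was -0.16. Leaving out WT library 1 or 3 ended the calls of the heme list, with medians of -0.19 and -0.20, and of the NRF2 list, with a median of 0.35 in each case, both of which had an adjusted p of 0.0499 with all libraries. Leaving out WT library 2 ended those of the interferon and NRF2 lists, with medians of 0.73 and 0.39, and the heme median was then -0.32. With a term for Y-linked expression 2 of the 12 passed, hypoxia and glycolysis and trophoblast and placenta. That term is a mean over Y-linked members of the sex-linked list, so the loss of that list followed from the term. Summed Y-linked levels were 72.25 to 115.4 CPM in WT and 44.74 to 65.22 CPM in the libraries labelled DKO. The term is thus partly confounded with group. Other splits of the 6 libraries into 3 and 3 gave between 6 and 14 lists.

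**Figure D3:**
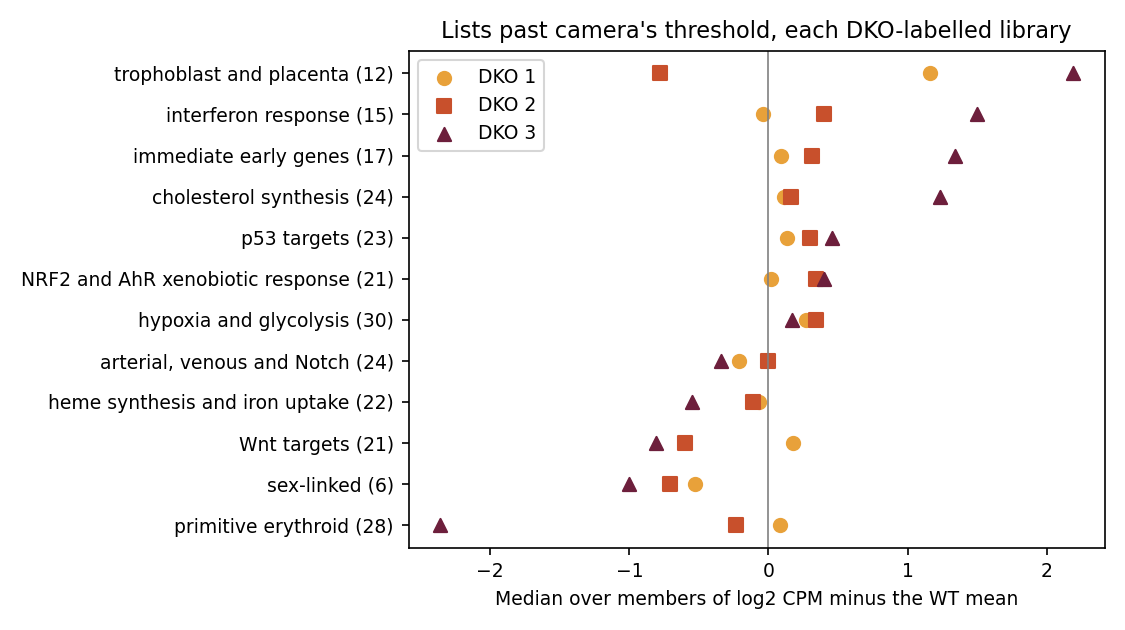
For each list past the threshold of camera (tested members in parentheses), the median over members of log2 CPM minus the WT mean in each of the 3 libraries labelled DKO. Primitive erythroid genes lie at 0.08, -0.23 and -2.36 in libraries 1, 2 and 3, and hypoxia and glycolysis genes at 0.27, 0.34 and 0.17.

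Neither list of homeobox genes passed camera. Of Hox genes 1-4, 8 were tested and 5 were positive (adjusted camera p 0.724), with Hoxb4 at -0.19 (SE 0.24) and Hoxb2 at -0.17 (SE 0.33). Of Hox genes 5-13, 10 were tested and 6 were negative (adjusted p 0.29), with Hoxc8 at -0.06 (SE 0.24) and Hoxb8 at -0.04 (SE 0.26). Haematopoietic progenitor genes had 13 of 25 positive (adjusted p 0.616), with Nfe2l1 at 0.04 (SE 0.10) and the core-binding factor subunit Cbfb at -0.23 (SE 0.10). Endothelial genes had 18 of 31 positive (adjusted p 0.757), with Lyve1 at 0.20 (SE 0.19) and VE-cadherin, Cdh5, at 0.12 (SE 0.20). Lyve1 stood at 0.39 without library 1 labelled DKO, past the threshold (adjusted p 0.0492 by edgeR), and at 0.05 without library 3. Signs of these small values, other than that of Cbfb, turned under some alternatives.

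Visceral endoderm genes had 26 of 43 positive (median 0.06, adjusted camera p 0.616). At an unadjusted p under 0.05 by edgeR, 2 members were higher and 7 lower, where 1273 of all 14002 genes were under it. DESeq2 called 1 member higher and 1 lower. The secreted carrier Afp stood at 9890, 6800 and 7900 CPM in WT and at 2260, 11500 and 30400 CPM in libraries 1, 2 and 3 labelled DKO (log2 fold change 0.88, SE 0.80), and the apolipoprotein gene Apob at -0.35 (SE 0.18). The ratio of counts of the embryonic globins Hbb-bh1 and Hbb-y was 1.34, 1.97 and 1.83 in WT and 5.4, 1.1 and 0.521 in libraries 1, 2 and 3 labelled DKO. Lin28b, an RNA-binding protein of early development, stood at 23.1, 31.2 and 29.6 CPM in WT and 45.3, 15.2 and 2.94 CPM in the libraries labelled DKO.

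**Figure D4:**
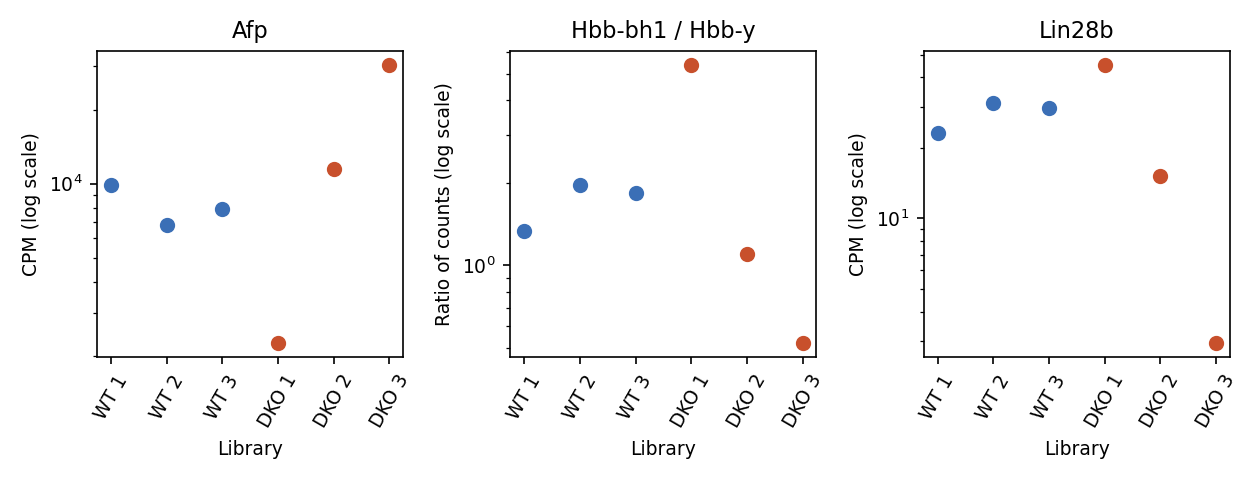
Afp and Lin28b in CPM and the ratio of Hbb-bh1 to Hbb-y counts, each on a log axis, in the 6 libraries (WT in blue, labelled DKO in orange). Libraries 1 and 3 labelled DKO lie on opposite sides of the WT libraries in each panel, with Afp at 2260 and 30400 CPM.

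The remaining lists did not pass camera with all libraries. Adjusted p was 0.815 for angiogenic signalling, 0.842 for extraembryonic mesoderm and mesothelium, 0.3 for extracellular matrix and adhesion, 0.247 for macrophage and myeloid and 0.336 for megakaryocyte genes. It was 0.757 for neural, 0.24 for somite and heart and 0.227 for caudal genes of the embryo proper, 0.392 for decidua and maternal leukocyte and 0.518 for parietal endoderm markers. It was 0.204 for BMP targets, 0.981 for the retinoid pathway, 0.761 for cell cycle, 0.616 for unfolded protein and integrated stress response and 0.623 for imprinted genes. Only 4 decidua and maternal leukocyte markers were tested, and adjusted over the list alone 3 were higher and 1 lower. DESeq2 called 0 of them. Their median difference from WT was 0.73, 0.03 and 1.57 in libraries 1, 2 and 3 labelled DKO. Of 16 parietal endoderm markers 1 was lower when adjusted over the list alone. Some of the lists that did not pass turned on single libraries. Somite and heart genes differed from WT by a median of 0.97, -1.59 and -1.53 in libraries 1, 2 and 3 labelled DKO, and without library 1 the list passed with a median of -1.37 against -0.25 (adjusted p 0.0065). Without that library macrophage and myeloid genes passed with a median of 1.12 against 0.73 (0.0063), megakaryocyte genes with 0.48 against 0.20 (0.013) and BMP targets with -0.37 against -0.08 (0.029). Somite and heart, macrophage and megakaryocyte genes also passed without WT library 1, with medians of -0.56, 0.94 and 0.45, and endothelial genes passed without library 2 labelled DKO, with a median of -0.19 against 0.02 (adjusted p 0.016). In the visceral endoderm, Hox 1-4 and retinoid lists the median and mean were positive and the direction of the test was down, and in the endothelial and progenitor lists the median was positive and the mean and test were negative.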

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

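The term for the Hbb-bh1 to Hbb-y ratio (the stage term), leaving out both libraries 1 and 3 labelled DKO, and thinning were chosen after seeing the data. Leaving out both leaves library 2 as the only library labelled DKO, and the spread then comes from the WT libraries alone. For that fit only fold changes and medians are given. The 5 called genes were all still called with other scaling factors, other filters, globin genes left out, robust shrinkage off, DESeq2, quality weights, the stage term, and without library 1 or 3 labelled DKO. Thinning and limma-voom each lost Vill, at 2.31 and 2.22 against 2.25. The sex term lost Cd276, Col4a6, Prkg2 and Vill, at -1.61, -4.98, -3.05 and 2.56, with adjusted p of 0.646 for the first 3 and 0.856 for Vill. Summed Y-linked levels did not overlap between the groups, so the sex term is partly confounded with group. The counts themselves ranged widely, and the causes were not tested.

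Genes higher numbered 177 with DESeq2, 1 with limma-voom, 1395 with quality weights, 560 with the stage term, 1 with the sex term and 1 at a threshold of 0.01. Genes lower numbered 119, 1266, 395, 351, 0 and 0 with DESeq2, quality weights, the stage term, both libraries left out, the sex term and the threshold of 0.01, and 5 with no filter. With edgeR and the sex term 365 genes had an unadjusted p under 0.05. Genes past 2-fold numbered 177 with DESeq2, 583 with quality weights, 271 with the stage term, 333 with both libraries left out, 1 with the sex term and 8 with no filter. The quality weights were 0.223 and 0.198 for libraries 1 and 3 labelled DKO and 1.27 to 3.7 for the others. Leaving out each library in turn gave from 0 to 433 genes higher, 0 to 201 lower and 0 to 321 past 2-fold.

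The same-numbered libraries did not deviate together (correlations of -0.37, -0.28 and -0.19), and no sample correlated best with its own number. Deviations from the means of 3 libraries are tied together within each group, so these correlations cannot exclude pairing. With the replicate block 1 gene was higher, 0 lower and 1 past 2-fold, with 762 genes at an unadjusted p under 0.05, and 12 lists passed. Rpl21 was the gene still called, and Cd276, Col4a6, Prkg2 and Vill were not, at -1.51, -5.27, -2.78 and 2.25 (adjusted p 0.601, 0.404, 0.427 and 0.601).

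Lists passing camera numbered 5 with the sex term, of which 2 were among the 12, and 0 with an estimated correlation or with fry. Leaving out each library in turn gave from 4 to 13. The lists gained with the sex term were haematopoietic progenitor, extracellular matrix and adhesion, and caudal genes. Their medians were 0.43, 0.21 and -0.59 (adjusted camera p 0.0355, 0.0157 and 0.0377), against 0.02, 0.17 and -0.47 without the term. The calls of the heme and NRF2 lists also ended with DESeq2 size factors, upper-quartile factors, globin genes left out, the CPM filter and shared members left out, that of the interferon list with the CPM filter, that of the heme list with the stage term, and that of the NRF2 list with no filter and with thinning. Quality weights ended those of the heme, arterial and trophoblast lists. Somite and heart, macrophage and megakaryocyte lists passed with quality weights, with medians of -1.46, 0.77 and 0.56. DESeq2 gives no list test. The globin share difference of -0.414 percentage points ran from -0.569 to -0.211 without each library in turn.

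None of the 5 called genes changed sign under the alternatives run, while fold changes of other named genes did, and the direction of camera turned in 8 lists that passed with all libraries or under the alternative, 6 of them among the 12. With the sex term log2 fold changes were -0.10 for Fdps, -0.25 for Tap1, -0.07 for Lyve1, -1.46 for Afp, 0.13 for Hoxb4, 0.31 for Hoxb2, 0.58 for Hoxc8 and 0.34 for Hoxb8. Without library 3 labelled DKO they were -0.03 for Nfe2l1, -0.25 for Afp, 0.10 for Hoxb2, 0.16 for Hoxc8 and 0.13 for Hoxb8. Over the libraries left out in turn the highest or lowest values were 0.08 for Nfe2l1, 1.38 for Afp, -0.51 for Hoxb2, -0.26 for Hoxc8 and -0.34 for Hoxb8, all without library 1 labelled DKO. Nfe2l1 stood at -0.02 without WT library 3 and -0.01 with quality weights, Cdh5 at -0.07 without library 1 labelled DKO, and Hoxb8 at 0.01 without WT library 2 and 0.04 without library 2 labelled DKO. Afp stood at -0.04 with the stage term and Hoxc8 at 0.05 with both libraries left out. Where the direction of camera turned, list medians with the sex term were 0.10 for primitive erythroid, 0.43 for haematopoietic progenitor, -0.17 for cholesterol synthesis, 0.19 for Wnt targets, -0.25 for interferon response and -0.01 for NRF2 and AhR. With both libraries left out they were 0.29 for endothelial and -0.88 for trophoblast markers, and with quality weights 0.27 for endothelial. The progenitor and endothelial medians were 0.02 with all libraries, so there only the direction of the test turned. Medians of lists that did not pass also crossed 0 under some alternatives. The causes were not tested. Over all alternatives the called genes kept direction, with 73 values past the threshold and 27 no longer past it.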

Other observations

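Chosen only after the result was seen were the tests of blood loss, of stage, of the place of genes near Cdx1 and Cdx2, of Cdx2 exons and of Esr1, the comparison with reassigned stage values, the stage term and thinning.

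With the ratio of Hbb-bh1 to Hbb-y as a term in edgeR, several of the fixed lists held called members. Visceral endoderm, a list of 43 tested genes, went both ways, with 6 higher and 5 lower. Of 21 Wnt targets 6 were lower, of 30 hypoxia and glycolysis genes 8 were higher, and of 21 NRF2 and AhR genes 6 were higher and 2 lower. Of 24 arterial, venous and Notch genes 3 were lower, and of 28 primitive erythroid genes 0 were called. Hbb-bh1 and Hbb-y belong to the primitive erythroid list, so the result for that list cannot be read apart from the term. In all, 560 genes were higher and 395 lower.

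Library 3 labelled DKO stood apart, at a root mean square distance from WT of 0.87 log2 units against 0.55 for library 1 and 0.52 for library 2. Depth alone is argued against, since the ratio of its distance to the next largest was 1.62 after thinning and 1.58 before. Loss of blood cells alone is argued against, since visceral endoderm genes moved apart (SD of the difference 1.33, highest WT 0.32), with 10 members above 1 log2 unit and 4 below -1. A difference in developmental stage may contribute, as a hypothesis: over the 6 libraries Afp fell in rank exactly as the globin ratio rose (rho -1, exact permutation p = 0.0028, Benjamini-Hochberg 0.0037 over 4 tests of 2 relations; Pearson r -1, exact p = 0.0014). Without libraries 1 and 3 labelled DKO rho was -1 and r -0.99, with an exact p of 0.083 at n = 4, and genotype, strain and tamoxifen, which the design leaves together, could each alter stage. The relation was chosen after its values were seen, which the adjustment does not cover. The first principal component (58.4% of the variance) placed the libraries in nearly the same order as Afp. Other measures that follow this component could give a similar rho, so these p-values do not single out stage.

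As a hypothesis, such a stage axis may hide differences between the groups. The stage term gave 955 genes against 5 without it. In 100 reassignments of the same stage values to libraries the median was 1 gene, but 4 gave as many and the highest gave 2856, so a large count is not special to this term. The term was measured from the same libraries, and if the mutation itself alters stage the term removes part of its effect.

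Genes that separated the groups lay near Cdx1 and Cdx2 more often than others. Of 68 genes with an unadjusted p under 0.001 and groups that did not overlap, 6 lay within 10 Mb (8.82%), against 1.67% of the other genes with a position (odds ratio 5.69, 95% interval 1.99 to 13.3, Fisher's exact one-sided p = 0.0011). Without Rpl21, whose place had been noticed first, the odds ratio was 4.74 (1.47 to 11.8, exact p = 0.0056), with Slc46a3 at 1.06, Mtus2 at 1.76 and Hmgb1 at -0.89 near Cdx2 and Tubb6 at 1.12 and Poli at 0.96 near Cdx1. Chromosome 5 held 11 of the 68 genes, and chromosome 8, the next, held 5. Of those on chromosome 5, 4 lay in the window around Cdx2, and others such as Prkg2 lay outside it. Tubb6 and Poli start at 67390731 and 70508680 on chromosome 18, in the outer part of the window around Cdx1. Fisher's test takes genes as independent, but Slc46a3, Mtus2 and Hmgb1 lie together on chromosome 5, from 147875897 to 149053057. Linked neighbours may change together, so these p-values may be too small and the intervals too narrow. A candidate explanation is DNA carried along with the mutant alleles from another strain, and local effects of the alleles stay open. Reads of Rpl21 copies that map differently between strains were not tested.

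Cdx2 counts were not lower in the libraries labelled DKO, with a log2 fold change of 0.38 (SE 0.12) that did not pass the threshold (adjusted p 0.449 by edgeR). With limma-voom and quality weights Cdx2 passed as higher, at 0.4 (adjusted p 0.0256). Counts over the whole gene cannot tell reads of remaining exons from an undeleted allele, which keeps that explanation open. Libraries without the Cre transgene are argued against by Esr1, whose sequence the receptor part of the transgene may share, with 2, 4 and 3 counts in WT and 64, 77 and 112 in the libraries labelled DKO (log2 fold change 3.98, SE 0.40). Its adjusted p by edgeR was 0.061, strain could alter Esr1 itself, and the presence of a transgene does not show that Cdx2 was recombined.

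Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 5 genes and the highest other 0, so 1 of the 10 gave as many, both for genes past the threshold and for those past 2-fold. For lists 5 of the 10 gave as many as the real 12, and the highest other gave 14.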
